A study of Mus musculus with 3 samples.

How the data were processed

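Gene expression was measured in 3 cultures of immortalized mouse skin lymphatic endothelial cells (imLECs), 1 culture each at passages 13, 14 and 18. The cells came from ImmortoMice, whose cells carry a temperature-sensitive SV40 large T antigen under an interferon-inducible promoter, and were isolated by fluorescence-activated sorting, per the labels. They were expanded at 33 °C with interferon-gamma, then moved to 37 °C without interferon-gamma for 3 days, per the labels' protocols. By those protocols, the move served to let the T antigen be degraded. RNA of the 3 cultures was extracted in parallel, amplified in 1 round of linear isothermal amplification and biotin-labelled as single-stranded cDNA, per the labels' protocols. The probe names are those of the Affymetrix mouse array, a 1-colour array on which each probe set reports one stretch of a transcript.

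The deposited table holds 1 signal intensity per probe set and array, on a linear scale. The submitters' processing notes name MAS5, without its role or version. The steps that made the intensity values are not given in the sources used here. The arrays' median intensities were 25.7, 26.0 and 26.3 at passages 13, 14 and 18, and their 95th percentiles were 1367, 1363 and 1365, so the deposited values were already on a common scale and were not normalized again. All 3 value columns were used. The table holds 45101 probe sets, of which 64 are the manufacturer's controls. The platform annotation gave 1 gene for 34958 probe sets and several genes for 932, and 9211 are unnamed here. Symbols were updated through Entrez identifiers to the RefSeq genes of assembly GRCm38.p6, which matched for 34754 of the probe sets with 1 gene. No genome build is named for the array values, so that assembly served only for names, chromosomes and gene order. Probe sets with several genes were given no gene name, which leaves Ccl21a and Ccl21b without a value.

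Intensities were taken to log2. Each of the 18194 genes was represented by its probe set with the highest mean log2 intensity over the 3 arrays, which favours the brightest probe set and can hide disagreement among probe sets. The deposited table used here holds no detection calls, so a floor was set on each array at the 95th percentile of 42 measured genes restricted to other tissues, such as albumin, rhodopsin and protamines. The floors were 29.4, 36.2 and 34.6 intensity units at passages 13, 14 and 18 (log2 4.88, 5.18 and 5.11). A gene above the floor on all 3 arrays was called detected. Of the reference list itself, Prm1 and Camk2a passed that call (2 of 42). A value under the floor sets only an upper limit on the transcript.

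There is 1 group and 1 culture per passage, so no test between groups was made. The share of detected genes in each of 17 gene lists was set against 10000 random lists matched on the number of probe sets per gene, as a description of these arrays. The trend with passage number was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the 10490 genes whose mean log2 intensity lay above the mean floor. The fit leaves 1 residual degree of freedom per gene before the spread is shared across genes. P-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Lists with at least 3 tested genes and the 20 chromosomes other than Y were tested in both directions with limma's camera on the same fit at its preset inter-gene correlation, with camera at an estimated correlation and, for lists, fry beside it. The limma p-values of single genes measure only the spread among these 3 cultures, and the number of arrays limits the precision of every value. Camera at the preset correlation instead sets the genes of a list or chromosome against all other tested genes, treating genes as nearly independent. Its small p-values therefore do not measure how far cultures vary. RNA quality was read from the ratio of the 3' to the 5' control probe sets of Gapdh and Actb. Chromosome medians were taken over detected genes relative to the median of all detected genes on chromosomes, and set against 1000 circular shifts of the gene order.

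The gene lists, the tests of genes, lists and chromosomes over passage and the rule for named genes were fixed before the data were examined. The differences between pairs of passages, the shifts of the gene order and most tests of explanations were chosen afterwards. The rule names 30 markers of 7 cell type lists, the first 4 detected and first 2 undetected members of every other list, and the 10 detected genes with the largest moderated statistic in each direction of the passage trend. Genes outside the rule are named as examples within their list. Alternatives tried were the percentile and source of the floor, the median of a gene's probe sets, leaving out probe sets open to cross-hybridisation, quantile normalization, median centring, adding 16 before the log, no filter on dim genes, passage 18 against the mean of the other passages, no intensity trend, an estimated correlation and leaving out each culture in turn.

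The trend test was tested on simulated data made from the 10490 tested genes with 200 changed genes, in 20 runs. With the spread of the data, it called 0% of genes with a slope of 0.2 log2 units per passage, 37.5% at 0.8 and 91.9% at 1.6, with 5.6 false calls per run. With 0.2 of that spread, it called 88% at 0.2, with 11.8 false calls per run. For a simulated list of 33 genes, camera at the preset correlation called a slope of 0.05 in 65% of 20 runs and one of 0.15 in 100%, and camera at an estimated correlation called neither in any run (0%). At the preset correlation 0 unchanged lists were called. The estimated correlation in the data was 0.846 for cell cycle and 0.289 for fibroblast genes. With 1 residual degree of freedom it reflects only how many residuals of a list share a sign. It does not measure how closely the genes vary together. The simulated genes were drawn independently of each other, so these runs cannot show how often lists of correlated genes are called falsely.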

Results

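Transcript levels were measured on 1 array for each of 3 cultures of immortalized mouse skin lymphatic endothelial cells, taken at passages 13, 14 and 18 after 3 days at 37 °C. The series profiles these cells as a single group. The questions it allows are which lineage and pathway genes the cells express and how far cultures of different passage number differ. Of 18194 genes, 9848 (54.1%) were detected, that is, lay above the floor on all 3 arrays. The number of genes above the floor was 10802 at passage 13, 10268 at passage 14 and 10454 at passage 18. Levels are given below as log2 signal intensity, mean ± SD over the 3 cultures (n = 3), and each passage is a single culture without a replicate of its own.

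The cultures expressed most of the lymphatic endothelial list, with 15 of 21 measured genes detected. Pdpn (podoplanin) was at 11.65 ± 0.65 (SD, n = 3). Flt4, the receptor for the lymphangiogenic factor VEGF-C, was at 10.57 ± 0.63. Nr2f2, a transcription factor of venous and lymphatic endothelium, was at 10.41 ± 0.13, and Nrp2, a co-receptor of Flt4, was at 9.66 ± 0.47. The transcription factors Foxc2 and Sox18 were at 9.19 ± 0.99 and 9.12 ± 1.20. Lyve1, a hyaluronan receptor of lymphatic vessels, had the widest spread of the fixed lymphatic markers, 9.76 ± 2.16, with 10.43 at passage 13, 11.52 at passage 14 and 7.35 at passage 18. Both Lyve1 probe sets gave this order. Prox1, the transcription factor that specifies lymphatic identity, was close to the floor: its brightest probe set read 6.20 and 5.60 at passages 13 and 18, above the floors of 4.88 and 5.11, and 5.11 at passage 14, below the floor of 5.18. A second Prox1 probe set was above the floor on all 3 arrays, at 5.88, 5.28 and 5.71, and the third was below it on all 3. Itga9, Mmrn1 and Reln were below the floor on all arrays. The 15 detected genes compare with a median of 13 in random lists and stand at the 81.5th percentile of them, so the list as a whole was not detected more often than chance lists. Detection of Prox1 turned on the settings, since it was called on all 3 arrays with the floor at the 90th percentile or with the median of its probe sets.

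Genes shared by all endothelium were expressed almost without exception, with 31 of 33 detected against a median of 18 in random lists (100th percentile). The vascular cadherin Cdh5 was at 10.69 ± 0.32 and Pecam1, an adhesion molecule of endothelial junctions, at 10.56 ± 0.51. The transcription factor Erg was at 10.88 ± 0.37, and the receptor genes Kdr, Tek and Tie1 were at 9.86 ± 0.74, 9.18 ± 0.27 and 7.88 ± 0.35. The 2 genes not detected, Nos3 and Rasip1, were above the floor at passages 13 and 14 and below it at passage 18. Of the blood endothelial list, 12 of 21 genes were detected, at the 68.6th percentile of random lists. Efnb2, a ligand of arterial endothelium, was at 10.75 ± 0.63, Nrp1 at 10.24 ± 0.91, Plvap, a protein of fenestral diaphragms, at 9.67 ± 0.70 and Flt1 at 6.99 ± 0.77. Vwf, Dll4, Gja5 and Sox17 were below the floor on all arrays.

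Of the leukocyte list 4 of 19 genes were detected, at the 0.2nd percentile of random lists. The pan-leukocyte gene Ptprc was below the floor on all arrays, whereas Cd68, a lysosomal protein of macrophages, was detected at 6.93 ± 1.04. Of the keratinocyte and epithelial list 3 of 14 genes were detected (0.54th percentile), and Krt14 and Cdh1 were below the floor on all arrays. Of the mural and smooth muscle list 4 of 12 genes were detected (3.62nd percentile), among them Acta2, smooth muscle actin, at 10.38 ± 2.05, and Pdgfrb at 6.67 ± 0.89. Only the brightest Acta2 probe set, one open to cross-hybridisation, was above the floor on all arrays, and the other 2 were above it at passage 18 alone. Of the fibroblast list 9 of 16 genes were detected, equal to the median of 9 in random lists, among them Col1a1, a chain of type I collagen, at 8.28 ± 1.87, while Pdgfra was below the floor on all arrays. Of the sex-linked list, the X-chromosomal Xist was at 10.46 ± 0.10, and the 3 measured Y-linked genes, Kdm5d, Uty and Eif2s3y, were below the floor on all arrays.

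**Figure D1:**
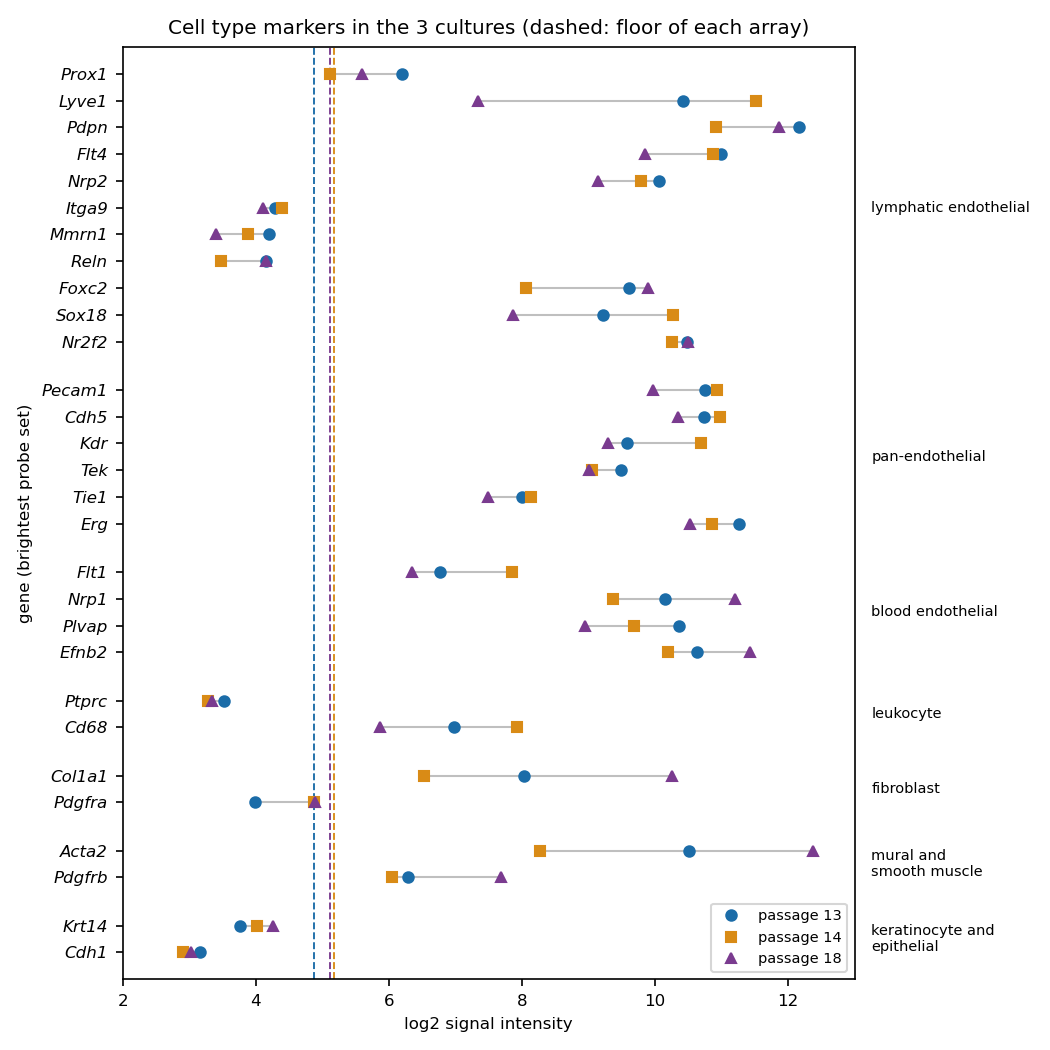
Log2 signal intensity (horizontal axis) of the 29 measured cell type markers fixed in advance (vertical axis, grouped by cell type), with 1 point per culture at passages 13, 14 and 18 and a dashed line at each array's floor. Pan-endothelial markers such as Pecam1 (9.97 to 10.94) lie far above the floors of 4.88 to 5.18, Prox1 lies near them, and Ptprc, Krt14 and Cdh1 lie below them.

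Of the functional lists, 4 were detected in full: cell cycle, p53 targets and cell cycle inhibitors, heat shock and housekeeping. All 26 measured cell cycle genes were detected, with Mki67, a marker of cycling cells, at 8.14 ± 1.07, Cdk1 at 9.13 ± 0.93, Top2a at 8.47 ± 0.97 and Ccnb2 at 8.62 ± 1.33. All 18 measured p53 targets and cell cycle inhibitors were detected as well, with Mdm2 at 12.12 ± 0.19, Cdkn1a (p21) at 11.39 ± 0.16, Cdkn2b at 10.40 ± 0.20 and Cdkn2a at 7.97 ± 0.34. Heat shock genes (14 of 14 detected) and housekeeping genes (19 of 19) were likewise complete. Hspa8 was at 13.47 ± 0.08, Hsp90aa1 at 11.46 ± 0.25, Hspa1b at 9.47 ± 0.22 and Hspa1a at 7.18 ± 0.20. The housekeeping genes Actb, Gapdh, Tubb5 and Eef1a1 had SDs between 0.01 and 0.03. Of the endothelial to mesenchymal transition list, 15 of 16 genes were detected (99.8th percentile of random lists), including the transcription factors Snai2 (10.10 ± 1.10), Zeb1 (9.67 ± 0.21), Zeb2 (8.43 ± 0.60) and Twist2 (6.28 ± 0.88), while Snai1 was above the floor on 2 of 3 arrays.

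Of the interferon response list, 19 of 26 genes were detected (99.2nd percentile of random lists), among them Ifit1 at 10.09 ± 0.83, Ifit2 at 9.24 ± 0.34, Irf1 at 8.02 ± 0.26 and Irf7 at 6.60 ± 1.36. Cxcl9 and Mx1 were below the floor. Of the Toll-like receptor pathway, 11 of 17 genes were detected (83rd percentile). Tlr3, a receptor for double-stranded RNA, was at 10.42 ± 0.28, the lipopolysaccharide receptor Tlr4 was at 9.93 ± 0.29 and its co-receptor Ly96 at 9.26 ± 0.25, and Tlr2 was at 7.12 ± 0.06. Tlr1 and Tlr5 were below the floor. Of the chemokine, cytokine and adhesion list, 14 of 22 genes were detected (80.5th percentile), with Ccl2 at 9.97 ± 1.25, Ccl5 at 8.79 ± 0.64, Cxcl1 at 7.91 ± 0.45 and Ccl7 at 6.76 ± 0.31, and with Ccl20 and Cxcl5 below the floor. Of the immediate early list, 13 of 18 genes were detected (98.6th percentile), with Jund at 11.61 ± 0.37, Jun at 9.87 ± 0.39, Egr1 at 8.99 ± 0.45 and Fos at 7.26 ± 1.06, and with Fosb and Junb below the floor.

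The 3 cultures were similar across the array, and the cultures of passages 14 and 18 differed most. Over all probe sets, log2 intensities correlated with Pearson's r of 0.984 between passages 13 and 14, 0.986 between 13 and 18, and 0.973 between 14 and 18 (Spearman's rho 0.979, 0.981 and 0.969). These are correlations across probe sets, which are not independent replicates. Among detected genes, 525 differed at least 2-fold between passages 13 and 14, 461 between 13 and 18 and 1200 between 14 and 18. The SDs of the log2 differences were 0.495, 0.466 and 0.698 for the same pairs. The culture of passage 13 held the middle value for 50.9% of detected genes, where chance gives 33.3%, so differences between the cultures did not follow passage number alone. The passage 18 array stood apart in its RNA quality controls. Its Gapdh 3'/5' signal ratio was 19.4, against 8.59 at passage 13 and 7.10 at passage 14, and its Actb ratio was 1.42, against 1.18 and 1.20.

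The pan-endothelial list fell with passage number, with a negative slope in 29 of 33 genes and a median of -0.14 log2 units per passage (camera adjusted p = 3.1e-09, adjusted p = 0.640 with an estimated correlation). At passage 18, 30 of the 33 genes were lower than at passage 13, with a median difference of -0.63, and 30 of 33 were lower than at passage 14, with a median of -0.94. Lmo2, a transcriptional cofactor of endothelial and blood progenitors, was 2.67-fold lower at passage 18 than at 13, Egfl7 2.33-fold, Esam 2.18-fold, Robo4 2.14-fold and Pecam1 1.72-fold lower, and Emcn was 1.34-fold lower. Tal1, Calcrl and Adgrf5 were the 3 genes higher at passage 18 than at 13. Without the passage 18 culture the median slope was 0.191, so the direction rests on that culture, whose Gapdh 3'/5' ratio was 19.4. No single member passed in limma, either over all genes tested (0) or adjusted over the list alone (0), and 5 had an unadjusted p under 0.05.

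The lymphatic and blood endothelial lists did not pass (camera adjusted p = 0.454 and 0.442, and 0.640 for both with an estimated correlation). In the lymphatic list the median slope was 0.01 and the mean slope -0.05, so they differ in sign. Between passages 13 and 18 Lyve1 was 8.44-fold lower, Sox18 2.55-fold lower and Flt4 2.22-fold lower, and Maf was 3.06-fold higher by its brightest probe set. The other Maf probe sets above the floor on all arrays read 6.35 and 5.53 at passage 13 and 6.55 and 5.44 at passage 18. The rest were above the floor at passage 18 alone or below it on all arrays. In the blood endothelial list the median slope was -0.11. Plvap was 2.65-fold lower at passage 18 than at 13, and Nrp1 and Efnb2 were 2.06-fold and 1.74-fold higher.

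Fibroblast genes moved in the other direction. The list rose with passage, with a positive slope in 8 of 10 tested genes and a median of 0.29 log2 units per passage (camera adjusted p = 1.2e-04, adjusted p = 0.640 with an estimated correlation). At passage 18, Col1a1 was 4.67-fold higher than at 13, Col6a1 4.53-fold, Col3a1 3.90-fold and Mmp2, a matrix metalloproteinase, 2.43-fold higher, whereas Thy1 and Fbln1 were 1.45-fold and 1.86-fold lower. The passage 14 culture lay on the other side, with a median difference from passage 13 of -0.83, and without passage 18 the slope of the list was that value, so its direction also rests on the array with the Gapdh ratio of 19.4. The mural and smooth muscle list did not pass (median slope 0.19, camera adjusted p = 0.0771). Acta2 was 3.61-fold and Pdgfrb 2.65-fold higher at passage 18 than at 13, and Tagln was 2.58-fold lower. The endothelial to mesenchymal transition list had a median slope of 0.06 and did not pass (camera adjusted p = 0.0573). Snai2 was 2.42-fold, Cdh2 2.07-fold and Fn1 1.47-fold higher at passage 18 than at 13, and Tgfb1 and Tgfbr2 were 2.76-fold and 1.53-fold lower.

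Proliferation genes were highest at passage 14. All 26 cell cycle genes were higher at passage 14 than at 13, with a median log2 difference of 1.20, and 24 of 26 were lower at passage 18 than at 14, with a median of -1.53. Ccnb2 was 3.39-fold, Mki67 2.98-fold and Tk1 2.86-fold higher at passage 14 than at 13, and the replication gene Mcm6 was 1.01-fold higher. Over passage number the list fell (median slope -0.16, negative in 23 of 26 genes, camera adjusted p = 1.6e-03, adjusted p = 0.640 with an estimated correlation). Without passage 18, the array with the Gapdh ratio of 19.4, the slope was 1.20. The p53 targets and cell cycle inhibitors lay the other way: 17 of 18 were lower at passage 14 than at 13, with a median of -0.22, and 14 of 18 were higher at passage 18 than at 14, with a median of 0.45. Fas, a death receptor induced by p53, was 6.51-fold higher at passage 18 than at 14, and Bbc3 was 1.32-fold lower. The trend of that list with passage did not pass (median slope 0.05, camera adjusted p = 0.0571).

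Interferon response genes fell with passage, with a negative slope in 17 of 20 tested genes and a median of -0.18 (camera adjusted p = 1.5e-04, adjusted p = 0.640 with an estimated correlation). The median difference was 0.44 between passages 14 and 13 and -0.93 between 18 and 13. Rsad2 was 4.37-fold, Ifit3 3.41-fold, Oasl2 2.75-fold and Usp18 2.55-fold lower at passage 18 than at 13. Without passage 18 the median slope was 0.44. The Toll-like receptor list fell by a smaller step (median slope -0.05, negative in 11 of 12 genes, camera adjusted p = 0.0327, adjusted p = 0.640 with an estimated correlation). Tirap was 1.56-fold and Tlr3 1.44-fold lower at passage 18 than at 13. Its slope was 0.07 without passage 18, and its call was lost with no filter on dim genes (adjusted p = 0.439). The leukocyte list, represented by Cd68, Coro1a, Cd53 and Lyz2, fell as well (median slope -0.21 over 4 genes, camera adjusted p = 0.0228, adjusted p = 0.640 with an estimated correlation). Cd53, a tetraspanin of leukocytes, was 3.78-fold lower at passage 18 than at 13. That call was also lost with no filter (adjusted p = 0.475), and its median slope was -0.28 without passage 18. The Gapdh ratio of the passage 18 array was 19.4.

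The remaining lists did not pass. Housekeeping genes had a median slope of -0.01 (camera adjusted p = 0.0709), chemokine, cytokine and adhesion genes of 0.06 (0.250), and immediate early genes of -0.01 (0.583). Keratinocyte and epithelial genes had a median slope of 0.05 (0.456). Heat shock genes had a median slope of -0.002 and a mean slope of 0.03, which differ in sign (camera adjusted p = 0.456). In the called lists 0 members passed in limma over all genes tested and 0 adjusted over the list alone, with 4 fibroblast, 4 interferon response and 1 leukocyte gene at an unadjusted p under 0.05. Of the 16 lists tested, 6 passed at the preset correlation, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.644. In simulated data, camera at an estimated correlation called 0% of the changed lists. Fry rests on the same 1 residual degree of freedom and was not tried on simulated data. The absence of calls in either test therefore cannot decide whether a list changed.

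**Figure D2:**
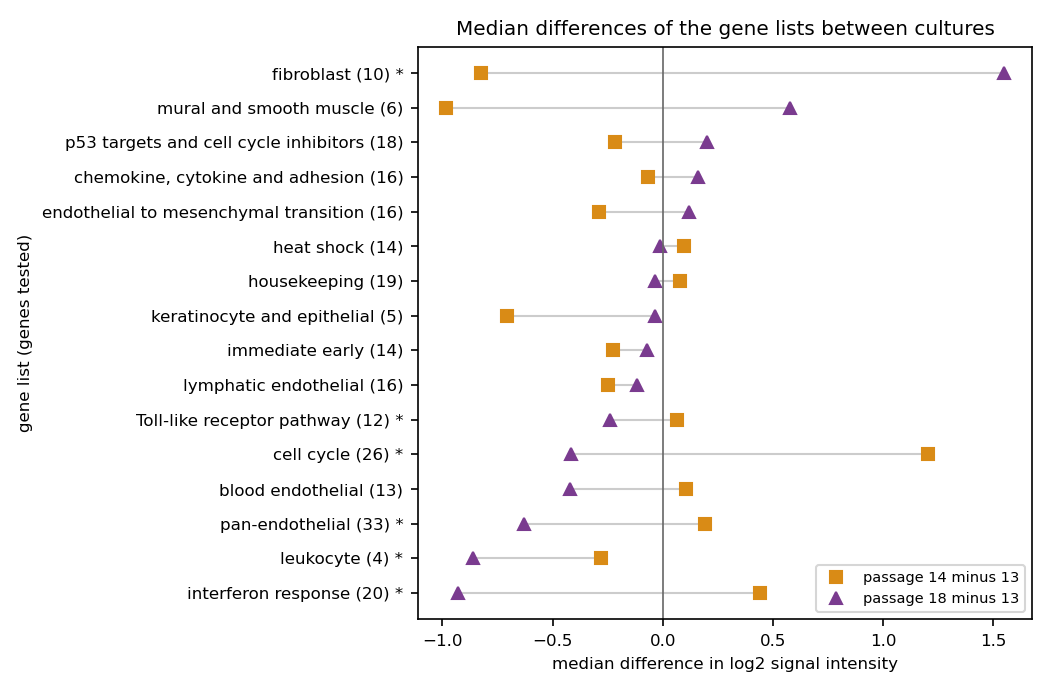
Median difference in log2 signal intensity from passage 13 (horizontal axis) of the tested genes of each list (vertical axis, number of genes in brackets) at passage 14 (squares) and passage 18 (triangles); asterisks mark lists that passed camera at the preset correlation. Cell cycle genes lie highest at passage 14 (1.20) and fibroblast genes at passage 18 (1.55), and 5 of the 6 marked lists have the triangle on the negative side.

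No single gene passed the trend with passage (limma, 0 of 10490 genes). At an unadjusted p under 0.05 there were 382 genes, where chance gives 524, and the smallest adjusted p was 0.903. The genes with the largest moderated statistics are therefore given as values only. Among those with positive slopes were Fzd2, a Wnt receptor (6.87 at passage 13, 7.29 at 14 and 9.28 at 18), the kinase gene Frk (5.72, 6.04 and 8.08), the transcription factor Pax9 (6.05, 6.03 and 8.36) and the collagen gene Col3a1 (7.63, 7.67 and 9.60). The other 6 were Antxr1, Psd3, Serpinb1a, Kcnip1, Pcdh18 and Sdc2, with slopes between 0.304 and 0.484. Among those with negative slopes were Arhgap25 (8.22, 7.75 and 6.27), Renbp (8.55, 8.13 and 6.69), Pde1a (9.45, 8.93 and 7.62) and Gfpt2 (9.87, 9.99 and 7.99). The others were Ttc9, Exoc3l2, Nectin2, Ap2s1, Mapk6 and Hebp1, with slopes between -0.419 and -0.281. All 20 stand apart at passage 18, the array with the Gapdh ratio of 19.4. This follows largely from the ranking, since with passages 13, 14 and 18 a large trend statistic needs similar values at 13 and 14.

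Gene expression shifted by chromosome between the cultures. Of 20 chromosomes, 12 passed camera for a trend with passage: 3, 8, 10, 16, 18 and 19 rose and 2, 7, 9, 11, 14 and X fell. None passed with an estimated correlation, where the smallest adjusted p was 0.376, and 6 passed with no filter on dim genes. Genes on chromosome 8 had a median log2 difference between passages 18 and 13 of 0.251 (1.19-fold), with 75.1% of 559 detected genes higher at passage 18 (camera adjusted p = 2.8e-06). Chromosomes 19 and 3 followed at 0.228 and 0.189. Chromosome 7 had a median of -0.198, with 29.6% of 686 genes higher at passage 18 (camera adjusted p = 5.8e-06), and chromosomes 14 and 9 had medians of -0.171 and -0.162. The SD of the 20 medians was 0.132, above the 95th percentile of 0.113 obtained when the gene order was shifted around the genome. Between passages 14 and 13 that SD was 0.052, below the corresponding 95th percentile of 0.080, and chromosome 4 had a median of -0.195. Of the called chromosomes, 2, 3, 7, 8, 9, 11, 18, 19 and X had a median of the opposite sign between passages 14 and 13. For chromosome 8 it was -0.023 and for chromosome 7 it was 0.020. Chromosomes 10, 14 and 16 kept their sign. The direction of most called chromosomes therefore rests on the passage 18 culture. Passage 18 is the array with the Gapdh ratio of 19.4.

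**Figure D3:**
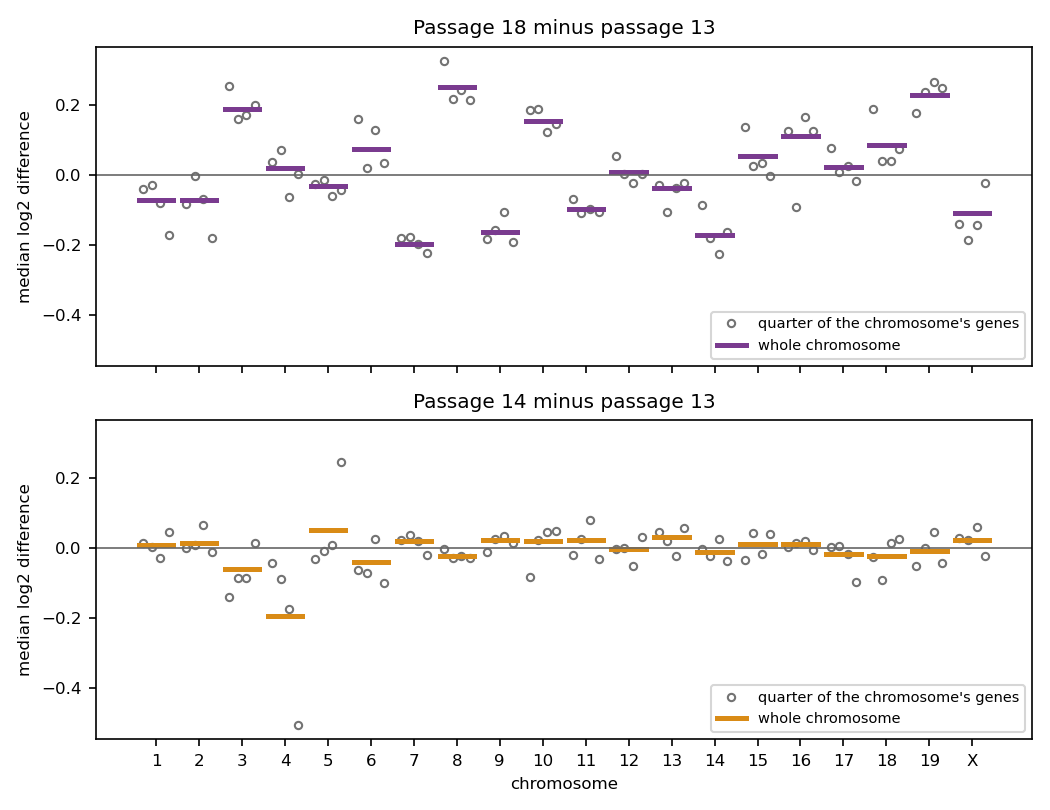
Median log2 difference from passage 13 (vertical axis) of detected genes on each chromosome (horizontal axis) at passage 18 (top) and passage 14 (bottom), relative to the median of all detected genes; bars are whole chromosomes and circles are 4 runs of equal gene number along each chromosome. At passage 18 the circles of chromosomes 3, 8, 10 and 19 lie above 0 and those of 7, 9, 11 and 14 below it, and at passage 14 the last circle of chromosome 4 lies at -0.504.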

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

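The differences between single pairs of passages and the values with the floor in place of lower ones were chosen after the results were seen. Of 641 values under other settings, outside the runs that left out a culture, 591 kept their direction and side of the threshold or stayed within the spread, and for 0 of the called results did the sign change. Quantile normalization gave 114 of the 591, although the arrays were already on a common scale. The count therefore does not measure robustness. No paired analysis was possible because there is a single group. With the floor at the 99th percentile, 1 leukocyte gene and 1 keratinocyte and epithelial gene were detected. With no filter on dim genes, the adjusted p was 0.475 for leukocyte and 0.439 for Toll-like receptor genes, p53 targets passed upward (0.0471), and 6 chromosomes passed. With quantile normalization, p53 targets passed upward (0.0354), and with median centring p53 targets and the endothelial to mesenchymal transition list did (both 0.0461). With passage 18 set against the mean of 13 and 14, 10 lists passed, adding p53 targets (0.0273) and, each at 0.0378, the mural and smooth muscle, endothelial to mesenchymal transition and housekeeping lists. With an estimated correlation 0 lists and 0 chromosomes passed, the adjusted p being 0.640 for the pan-endothelial, leukocyte, fibroblast, cell cycle, interferon response and Toll-like receptor lists. In simulated data that test called none of the lists that had been changed. The cause of the other differences was not tested. Leaving out each culture in turn, detected keratinocyte genes numbered 3 to 5. The median slope ranged from -0.234 to 0.191 for pan-endothelial, -0.827 to 0.390 for fibroblast, -0.383 to 1.20 for cell cycle, -0.288 to 0.443 for interferon response, -0.0965 to 0.0658 for Toll-like receptor and -0.280 to -0.172 for leukocyte genes. Of these, all but the leukocyte list changed sign without passage 18, where 1 passage separates the other cultures. Genes near the floor, such as Prox1, are limited by signal over background.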

Other observations

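The genes in this paragraph were chosen after their values were seen. Some genes were above the floor in 1 culture and below it in the others. At passage 14 Cxcr4, a chemokine receptor of endothelial tip cells, read 9.22 and was below the floor at passages 13 and 18, which makes it at least 20.3-fold and 17.2-fold higher at passage 14. Foxf1 (at least 9.54-fold over passage 13), Ocln (at least 7.83-fold) and Hoxd13 (at least 5.96-fold) had the same pattern. Lox, a collagen cross-linking enzyme, was below the floor at passage 14 and at least 15.9-fold higher at passage 13 and 17.5-fold higher at passage 18. At passage 18 Rspo2 and Elmod1 were at least 7.61-fold and 6.98-fold higher than at passage 13, where they were below the floor, and Nefl was below the floor, at least 8.12-fold lower than at passage 13. Of 33 Hox genes measured, 11 were detected, with Hoxd8 at 10.49, 10.83 and 10.61 and Hoxd10 at 9.63, 9.87 and 10.02 at passages 13, 14 and 18, and 7 were above the floor on 1 or 2 arrays. Hoxa9 was below the floor at passage 13 and at least 8.56-fold higher at passage 14.

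All tests in the next paragraphs were chosen after the result was seen, except those of RNA quality and of other orders of the passage numbers. For the 10490 genes of the passage trend, each of the 6 orders of the 3 passage numbers gave as many called genes as the real order (6 of 6), since the real order called 0 and the highest other 17. With 6 orders no share under 0.05 can be reached.

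Pan-endothelial genes were lower and fibroblast genes higher at passage 18. A lower share of endothelial cells cannot be told apart from other causes. The fibroblast list lay 0.973 log2 units above the mural list (95% bootstrap interval -0.366 to 2.48 over 16 genes). This gap cannot decide, since a gain of a single cell type need not raise the markers of other types alike. Its distance of 1.67 from the pooled leukocyte, mural and keratinocyte lists decides nothing either, since leukocyte and keratinocyte markers lay mostly near or under the floor. Within the fibroblast list, 8 of 10 tested genes were higher at passage 18 than at 13. Thy1 and Fbln1 were lower, and Pdgfra, Lum, Fap and Dpt were below the floor on all arrays. These comparisons replaced one fixed earlier, on the SD of single pan-endothelial genes (0.447 between passages 18 and 13, against 0.233 between probe sets of a gene), because a spread between single samples cannot be set against technical noise. Lower RNA quality cannot be told apart from a change in the cells. If the lists followed the log2 Gapdh ratio, their step from 13 to 14 would be -0.233 of that from 13 to 18. The lists gave -0.305 (pan-endothelial, interval -0.713 to -0.114) and -0.534 (fibroblast, -1.46 to 0.196), and both intervals hold -0.233. All bootstrap intervals given here resample the genes of a list on the same 3 arrays. They describe the spread among genes and do not measure how far cultures vary. The answer depends on the control. The log2 Actb ratio was 0.239, 0.268 and 0.503 at passages 13, 14 and 18, which makes its share positive. That sign rests on a small step between single arrays, from 0.239 to 0.268, and is uncertain. The pan-endothelial interval lies wholly below 0, whereas the fibroblast interval holds 0, and neither can decide the question. A gain of fibroblasts, in cells that had been isolated by sorting, and a shift of the cells themselves toward a mesenchymal program stay untested.

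Cell cycle genes were higher at passage 14. Interferon-gamma left from the earlier culture would raise its response genes and cannot be told apart from other causes. Among such genes, 3 of 9 were higher at passage 14 than at 13. Their median was -0.120, with a 95% bootstrap interval over genes of -0.230 to 0.243, which holds 0. That interval does not measure how far cultures vary. Of 9 genes of the type I interferon response, 9 were higher at passage 14 (median 0.908) and 9 lower at passage 18 (median -1.20) than at passage 13. Both sets were drawn from the interferon response list after the result was seen. They leave out the tested genes Cxcl10 (1.09 between passages 14 and 13) and H2-Ab1 (-2.19, to below the floor at passage 14). T antigen activity left in the passage 14 culture, which would block p53, cannot be told apart either: the median of the p53 target list lay at the 1.62nd percentile of random lists matched on signal, but the fibroblast, mural, endothelial to mesenchymal transition and keratinocyte lists lay lower, at 0, 0.05, 0.79 and 1.3. The levels of T antigen and the density of the cultures were not measured here and stay open.

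Expression at passage 18 was shifted along the length of several chromosomes. A change of chromosome copy number in that culture may be a candidate explanation: 15 of 20 chromosomes had all 4 runs of equal gene number on one side of 0, against a median of 10 when the gene order was shifted, and 7 of 1000 shifts gave as many. These 15 include chromosomes 1, 5, 6 and 13, which did not pass camera, and the shift of chromosome 5 was only -0.030. Chromosome 16, which passed, had a run on the other side, at -0.090. Any other cause acting along whole chromosomes would give the same count, so it cannot single out copy number. The RNA quality of the passage 18 array was not tested for the chromosomes. Co-expression of neighbouring genes would stay within the shifted orders, but the SD of the medians, 0.132, lay above all 1000 of them (highest 0.128), and so did the SD left after a trend on gene density was removed, 0.128 (highest 0.125), while GC content was not tested. At passage 14 a step ran along the end of chromosome 4, where the 201 detected genes from Bsdc1 to Samd11 had a median of -0.50 (0.709-fold) against passage 13 and 87.6% were lower. Its lowest run of 100 neighbouring genes reached -0.575. The largest on any other chromosome was 0.300, on chromosome 5, and outside both chromosomes the largest in size was 0.156. Chromosome 5 also had a step at its end, where the 126 genes from Polr2j to Rfc3 had a median of 0.294 at passage 14 against 13. The chromosome 4 run was picked as the lowest of all, so this gap alone cannot exclude co-expression. At passage 18 the chromosome 4 segment had a median of -0.011 against passage 13. A lower copy number of the segment in the passage 14 culture was not tested.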
